A study of Mus musculus with 12 samples.

How the data were processed

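RNA was sequenced from dermal macrophages of wild-type C57BL/6 mice, sorted from the dermis of the ear as cells with high surface CD64, the high-affinity Fc gamma receptor that marks macrophages and monocyte-derived cells. The cells came from uninfected skin or from skin taken 1, 5 or 7 days after Staphylococcus aureus strain Newman was injected into the dermis of both ears. Each of the 4 groups holds 3 libraries, named here by group and replicate number, so that 12 libraries enter every fit. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Libraries were made from polyadenylated RNA with random priming, per the labels' protocols, which state no step that marks strand. Reads from a gene and from an antisense gene that overlaps it can therefore not be told apart, and reads shared between near-identical genes of a family, such as the Gbp, Tgtp and Ly6 genes, may have been split or dropped.

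The authors deposited 1 table with a signal value per gene and library, the count of reads divided by 1 size factor per library, and 6 tables of their own comparisons between pairs of groups. The submitters' processing notes name bcl2fastq, cutadapt, FastQC, STAR 2.5.2b, DESeq2 and the mm10 genome build, without roles or order. The read counter and the gene annotation are not given in the sources used here. Each of the authors' deposited tables lists a base mean signal, a log2 fold change, its standard error, a Wald score, a p-value and an adjusted p-value per gene. Their sign runs from the first named group to the second, and it was turned here so that a positive value means higher at the later time. The signal table lists 42454 genes, of which 20841 are at 0 in every library. Of these, 36134 (85.1%) matched a RefSeq gene symbol of assembly GRCm38.p6, 3854 matched a synonym or a gene number, and 2466 matched nothing and were kept under the name in the table. Coordinates are of GRCm38.p6. No column of another sample was found.

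The values of a library are multiples of a single step, so the reads could be recovered. Divided by that step, 100.0% of the values in each library were whole numbers within a tolerance of 0.01. The recovered totals run from 21491956 to 32461714 reads per library. DESeq2 run on the recovered reads of each pair of groups gave the same totals of genes below an adjusted p of 0.05 as the authors' deposited tables in all 6 comparisons, 2809 for day 1 against control among them. Pairs of replicates differed by far more than counting noise, with a chi-square per degree of freedom from 24.34 to 311.37, so no pair of counts agreed within sampling noise. Repeat libraries of 1 pool would also differ by more than that.

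The test, the samples in each fit, the gene lists, the rule for named genes and all alternatives not described as chosen after seeing the data were set before the data were examined. Normalized counts were used as log2(value + 1), so the fold change of a gene with few reads is understated. Genes with at least 10 normalized counts in at least 3 libraries were tested, which left 13790. A linear model with 1 term per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in its moderated variance. The 6 differences between groups and an F test over the 4 groups were taken from it. Adjusted p-values follow Benjamini and Hochberg within each comparison, and genes below 0.05 are called higher or lower. Unless another tool is named, every adjusted p for a gene is from this limma fit. Levels are group means of normalized counts ± SD over 3 libraries, and a fold is 2 to the power of the fitted log2 change. Where all libraries of a group are at 0, the fold is a bound against a floor of 3 reads per library, which is 3.04 normalized counts in the control, 3.29 on day 1, 2.82 on day 5 and 2.78 on day 7. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

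Gene lists of 628 entries in 32 lists covered metabolism, inflammatory signalling, macrophage identity, dissociation stress and markers of other cell types that a CD64 gate could admit. All entries were found in the table, and 31 lists with at least 5 tested members were run. The list tests used camera, which asks whether the genes of a list moved more in 1 direction than other genes did, with a preset correlation between genes of 0.01. A repeat estimated that correlation from the libraries. The fry test, which asks whether a list's genes moved on balance in 1 direction without regard to other genes, was the other alternative. List p-values are adjusted over the 31 lists. For each list, genes were also counted with their p-values "adjusted over the list alone".

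The genes named in the text follow a rule with 3 parts. In each comparison, the 8 genes with the greatest rise and the 8 with the greatest fall were taken among genes below the threshold whose mean was at least 50 in the higher group and whose 3 values did not overlap between groups, an event that chance gives in 10% of genes. Gene models without a proper name were left out. For a list that is described, up to 4 members with the greatest change in its direction and 1 member with the greatest opposite change were taken. Finally, 21 genes chosen for their part in macrophage biology were followed throughout: Fcgr1, Adgre1, Csf1r, Csf2ra, Csf2rb, Hif1a, Acod1, Il1b, Tnf, Il6, Nos2, Arg1, Vegfa, Slc2a1, Tlr2, Ly6c2, Ccr2, Mrc1, Cd163, H2-Ab1 and Mki67. Other names are said to be chosen after their values were seen.

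Limma was run on simulated data for day 1 against control, which may lack the real day 1 spread. Among 13790 genes it recovered 19% of 100 genes changed 2-fold and 60% of 100 changed 4-fold, with 0.052% of unchanged genes called. There edgeR recovered 17% and 62%, and DESeq2 30% and 68% with 0.28% of unchanged genes called. Camera found a raised list and called 0 others, but genes of real lists correlate, so its false calls there stay unknown. Genes changed 2-fold were thus mostly missed, and a gene that is not called is not shown to be unchanged.

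The alternatives were quantile normalization, pseudocounts of 0.5 and 8, no filter, a filter of 50 normalized counts in 3 libraries, the replicate number as a block, edgeR 4.0.16 with TMM scaling and DESeq2 1.42.0 on the recovered reads, a fit of only the groups compared, each library left out in turn, and the authors' deposited tables. Array quality weights and a fit without the genes of a chromosome 17 stretch were chosen after seeing the data. So were fits without the day 1 libraries or without day 1 replicate 1 for the comparisons that do not use these libraries. Comparisons against the same control libraries share chance values, so the correlation of changes between days was set against 100 simulations of unchanged groups. For each pair of groups, the 10 ways to split its 6 libraries into groups of 3 were also run. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.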

Results

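The series profiles CD64-high dermal macrophages, the phagocytes of the skin's connective tissue, in uninfected mice and 1, 5 and 7 days after Staphylococcus aureus entered the dermis. Its title asks how these cells' metabolism is rewired during staphylococcal skin infection. Each group holds 3 libraries. They held 23336532 to 31929348 reads in the control, 21491956 to 30650282 on day 1, 29578639 to 32461714 on day 5 and 30534946 to 31885793 on day 7. The day 1 libraries held reads of fewer genes, 10965 in replicate 1, 13004 in replicate 2 and 13385 in replicate 3, against 14633 to 16851 in the control, 16184 to 17672 on day 5 and 16063 to 16829 on day 7. The 10 most abundant genes took 7.52% to 11.24% of the reads of a library. On the first principal component of the tested genes, which held 32.1% of the variance, day 1 replicate 1 lay at 230.8 and the other libraries between -38.83 and 32.32.

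**Figure D1:**
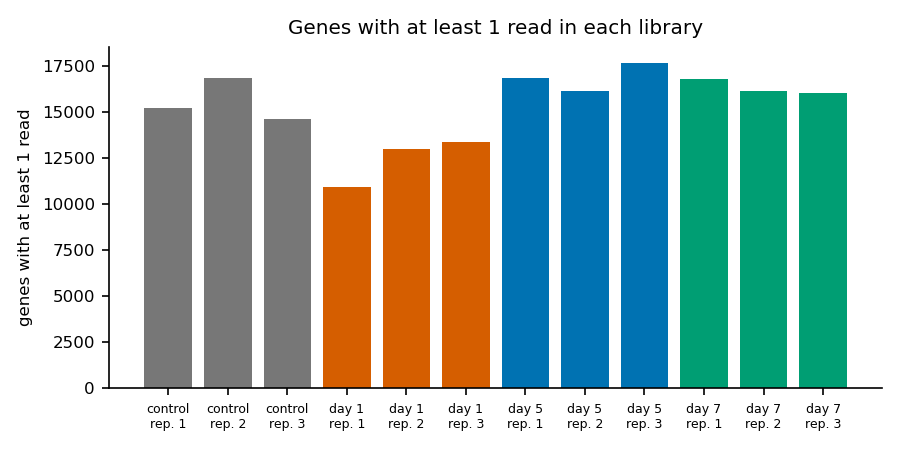
Number of genes with at least 1 read in each of the 12 libraries, coloured by group. The day 1 libraries lie lowest, from 10965 to 13385 genes, and the others hold 14633 to 17672.

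Among the 4 groups, 3879 of 13790 tested genes (28.1%) differed by limma's F test. Fcgr1, which encodes the CD64 used for the sort, was read at 722.5 ± 141 normalized counts in the control (SD, n = 3) and rose to 7366 ± 2833 on day 1, 5286 ± 2350 on day 5 and 9762 ± 2200 on day 7. Adgre1, which encodes the macrophage antigen F4/80, stayed between 15206 and 23462 with no call on any day. Markers of granulocytes and lymphocytes were mostly listed low in all groups, with exceptions such as Csf3r, which neutrophils share with monocytes, at 4106 already in the control, and Ighm of B cells at 518.9. The 18 neutrophil genes had a median level of 0 in the control, 4.22 on day 1, 4.96 on day 5 and 3.65 on day 7, and Ly6g, the surface antigen of neutrophils, reached at most 1.60. S100a8, made by neutrophils and by monocytes, reached 409.5 ± 174.7 on day 7 and S100a9 376.9 ± 206 on day 1. Cd3e of T cells was read at 46.55 ± 64.55 on day 1 and at most 5.14 in the other groups. The median over the T, natural killer and innate lymphoid genes was 2.36, 6.13, 1.85 and 5.14 in the order control, day 1, day 5 and day 7. That over the B cell genes, too few of which were tested for a list test, was 0.591, 0, 1.00 and 0. A value of 0, as for Trac, Ncr1, Pax5 and Elane in all libraries, does not show absence, since some genes that every cell uses are also listed at 0. Keratinocyte markers, which show carry-over of epidermis, were not called on any day, with medians of -0.32, -0.18 and -0.51 against the control (camera adjusted p = 0.725, 0.715 and 0.5), although on day 1 the test pointed up and on day 5 the mean was positive. For the lymphoid list on day 1 the median was positive but the mean and the test were not. The endothelial (0.217, 0.715, 0.837), dendritic and Langerhans cell (0.274, 0.385, 0.5), mast cell and basophil (0.292, 0.23, 0.5), lymphoid (0.938, 0.21, 0.736) and muscle, cartilage, Schwann cell and melanocyte lists (0.0904, 0.641, 0.759) were likewise not called against the control on days 1, 5 and 7, in that order of the adjusted p-values by camera.

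**Figure D2:**
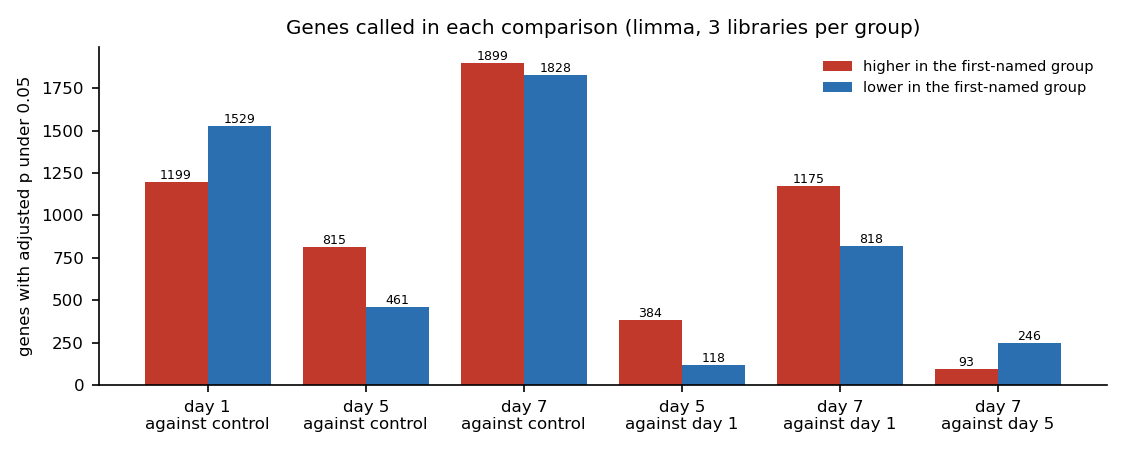
Bars give the number of genes called higher and lower by limma at an adjusted p below 0.05 in each of the 6 comparisons, 3 libraries per group. Day 7 against control has most, with 1899 higher and 1828 lower, and day 7 against day 5 has fewest, with 93 higher and 246 lower.

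The comparison of day 1 with the control asks what the macrophage pool expressed a day after infection. Of the lists, monocyte genes had the highest median. Ly6c2, a surface antigen of classical monocytes, went from 6.73 ± 6.55 to 3339 ± 1108 normalized counts (664-fold, adjusted p = 1.26e-05, or 1130-fold without control replicate 1 and 302-fold without control replicate 3). Chil3, a secreted chitinase-like protein of myeloid cells, rose 973-fold to 12403 ± 4555, and Ccr2, the chemokine receptor that draws monocytes out of blood and marrow, rose 22.0-fold to 1884 ± 850.6. Haptoglobin (Hp) had 0 reads in every control library and was at least 389-fold higher. Plac8 was at 1043 ± 296.3 against 0.623 ± 1.08, with 2 reads in the control group. Of 15 measured monocyte genes, 13 rose (13 adjusted over the list alone), with a median log2 change of 6.29 (camera adjusted p = 1.84e-20, adjusted p = 0.011 with an estimated correlation). Chil3, Fn1, Thbs1 and Clec4e of this list also stand on others.

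Enzymes that handle arginine and itaconate in inflammatory macrophages rose alongside. Arg1 (arginase) went from 5.58 ± 8.18 to 5306 ± 3925 (1100-fold, adjusted p = 3.2e-05). Its fold was 2350 without control replicate 1, 587 without control replicate 3, 2040 without day 1 replicate 1 and 730 without day 1 replicate 2. Nos2, the inducible nitric oxide synthase that competes for the same substrate, went from 8.97 ± 5.31 to 3966 ± 2154 (394-fold, adjusted p = 5.56e-07). Arg2 rose 287-fold (592-fold without control replicate 1, 116-fold without control replicate 3), Ass1, which resynthesizes arginine, 207-fold, and Acod1, which makes itaconate, 12.2-fold to 44452 ± 18860. Of the 14 genes of this list, which also holds prostaglandin and oxidative stress enzymes, 10 rose (11 adjusted over the list alone), with a median of 4.28 (camera adjusted p = 5.17e-13, adjusted p = 0.045 with an estimated correlation). Receptors that sense bacteria rose in 12 and fell in 1 of 21 (15 and 2 adjusted over the list alone, camera adjusted p = 1.22e-10, adjusted p = 0.045 with an estimated correlation). Among them the formyl peptide receptor Fpr2 rose 64.1-fold, the beta-glucan receptor Clec7a 14.8-fold and Tlr1 3.69-fold. Fpr1 was at 1525 ± 745 against 0.295 ± 0.512, with 1 read in the control group. Tlr2, a receptor for staphylococcal lipoproteins, was at 40163 ± 2259 against 40618 ± 2318 (log2 change -0.02, adjusted p = 0.959), with its sign turned without control replicate 3 (0.02) or day 1 replicate 2 (0.02).

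Cytokine genes rose in 12 of 17 (13 adjusted over the list alone), with a median of 1.94 (camera adjusted p = 5.98e-11, adjusted p = 0.06 with an estimated correlation). Il1b, a driver of neutrophil recruitment, rose 5.36-fold from an already high 37844 ± 3651 (adjusted p = 6.69e-05). Il6 rose 2.30-fold and the activin gene Inhba 259-fold (404-fold without day 1 replicate 1, 156-fold without day 1 replicate 3). Il12a, at 0 in the control, was at least 199-fold higher, or 108-fold without day 1 replicate 3. Of 21 chemokine genes 8 rose (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.59e-05, adjusted p = 0.2 with an estimated correlation), among them Cxcl9, which attracts T cells, 17.3-fold (8.61-fold without control replicate 1, 36.2-fold without control replicate 3, 27.1-fold without day 1 replicate 3) and Ccl6 4.58-fold. Type I interferon-stimulated genes rose in 15 and fell in 1 of 26 (20 and 3 adjusted over the list alone), with a median of 1.4 (camera adjusted p = 2.29e-10, adjusted p = 0.22 with an estimated correlation). Among them Oas3 rose 19.3-fold, Zbp1 16.7-fold and Irf7 13.7-fold, whereas Ifit1 fell 1.90-fold. Interferon gamma-induced genes rose in 13 of 22 (14 adjusted over the list alone, camera adjusted p = 7.44e-08, adjusted p = 0.2 with an estimated correlation), with Cd274, which encodes PD-L1, up 6.03-fold. NF-kappaB subunits and inhibitors rose in 8 of 19 (10 adjusted over the list alone, camera adjusted p = 1.28e-05, adjusted p = 0.2 with an estimated correlation), led by Traf1 at 6.88-fold. Phagocyte oxidase and antimicrobial genes rose in 4 of 12 (4 adjusted over the list alone, camera adjusted p = 0.000862, adjusted p = 0.2 with an estimated correlation), led by the protease inhibitor Slpi, up 120-fold from 144.8 ± 26.74.

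Of 18 glycolysis genes, 9 rose and 2 fell on day 1 (10 and 4 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.00015, adjusted p = 0.34 with an estimated correlation). Slc16a3, the lactate exporter, rose 12-fold from 552.3 ± 78.44, enolase (Eno1) 4.50-fold, pyruvate kinase (Pkm) 3.18-fold and the glucose transporter Slc2a1 3.09-fold (adjusted p = 0.000235). Hypoxia-induced genes other than glycolysis rose in 5 of 19 (6 adjusted over the list alone), Ddit4 10.3-fold, Vegfa 4.83-fold, Mxi1 4.07-fold and Bhlhe40 3.99-fold, and Hif1a, which encodes a hypoxia-inducible transcription factor, rose 4.14-fold. That list had a median of -0.23 but a mean of 0.07, and camera called it up (adjusted p = 0.043, adjusted p = 0.42 with an estimated correlation). The call was lost without control replicate 3 (0.059), day 1 replicate 1 (0.055) or day 1 replicate 2 (0.11), with replicates as a block (0.054) and with genes kept from 50 counts (0.11). In the tricarboxylic acid cycle, 4 of 17 genes rose (4 adjusted over the list alone), citrate synthase (Cs) 1.55-fold and malate dehydrogenase (Mdh2) 1.57-fold, with a median of 0.10 (camera adjusted p = 0.0387, adjusted p = 0.28 with an estimated correlation). Its call was lost without control replicate 1 (0.075), control replicate 3 (0.059), day 1 replicate 1 (0.12) or day 1 replicate 2 (0.076), and after quantile normalization (0.24). It was also lost with a pseudocount of 8 (0.055), with genes kept from 50 counts (0.11) and with only these groups fitted (0.065). Respiratory chain and ATP synthase genes (median 0.08), fatty acid oxidation (0.09), cholesterol efflux and lipid storage (0.17), lysosomal genes (-0.27), matrix and growth factor genes (0.07), the cell cycle (-0.37), MHC class II presentation (0.28, with a negative mean) and genes induced by tissue dissociation (-0.04) were not called, with camera adjusted p from 0.0934 to 0.741. Cholesterol synthesis was not called either (adjusted p = 0.0904), although 9 of its 22 genes fell and 1 rose.

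Resident dermal macrophage markers fell in 7 of 26 (10 adjusted over the list alone), with a median of -0.74 (camera adjusted p = 0.000862, adjusted p = 0.42 with an estimated correlation). Ltc4s, the leukotriene C4 synthase, fell 8.26-fold, the selenium carrier Selenop 4.31-fold, the lectin Fcna 3.06-fold and the scavenger receptor Stab1 2.28-fold. The mannose receptor Mrc1 (log2 change 0.21, adjusted p = 0.527) and the haemoglobin scavenger receptor Cd163 (0.20, adjusted p = 0.617) were not called, while Csf1r, the receptor for macrophage colony-stimulating factor, fell 1.96-fold. Several genes with a great fall were read at 0 in all day 1 libraries, which also held reads of the fewest genes. They include Ggnbp1 (91.5 ± 16.3 in the control, at least 27.8-fold lower), Kifc2, Amy1, Kyat1 and Nrg2, with bounds from 21.7-fold to 27.6-fold. Sema6a, at 3195 ± 627.8 in the control, fell 69.3-fold, a call lost without control replicate 2 (adjusted p = 0.0519). Its fold rests on day 1 replicate 1, where it had 0 reads, and was 10.3 without that library, 191 without day 1 replicate 2 and 170 without day 1 replicate 3. Interleukin 4 and alternative activation genes rose in 3 and fell in 2 of 16 (5 and 2 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0206, adjusted p = 0.21 with an estimated correlation). Beside Arg1 and Chil3, the cytokine-signalling inhibitor Cish rose 1.91-fold. The list's call was lost without day 1 replicate 1 (0.055) or replicate 3 (0.052) and with only these groups fitted (0.062). Among markers of other cells, neutrophil genes rose in 5 and fell in 1 of 9 (5 and 1 adjusted over the list alone, median 4.03, camera adjusted p = 3.3e-05, adjusted p = 0.045 with an estimated correlation), led by S100a9, at least 124-fold higher. Fibroblast genes were called up (median 1.10, camera adjusted p = 0.00669, adjusted p = 0.52 with an estimated correlation) with 1 of 16 genes past the threshold (1 adjusted over the list alone), a call lost without control replicate 3 (0.059) or day 1 replicate 3 (0.22) and with fry (0.27).

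In all, limma called 1199 genes higher and 1529 lower on day 1, 727 and 1056 of them at least 2-fold. The median log2 change of all tested genes was -0.20 here, 0.16 for day 5 against day 1 and 0.18 for day 7 against day 1, and -0.05, -0.02 and -0.04 after quantile normalization, so that a gene at -0.20 lies at the day 1 median. The total of 2728 fell to 1656 without control replicate 1 and to 1638 without control replicate 3. The authors' deposited table holds 1469 higher and 1340 lower. Of the genes that the 3 parts of the rule named and that were called, 15 of 16, 55 of 63 and 13 of 13 stayed below the threshold whichever single library was left out.

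**Figure D3:**
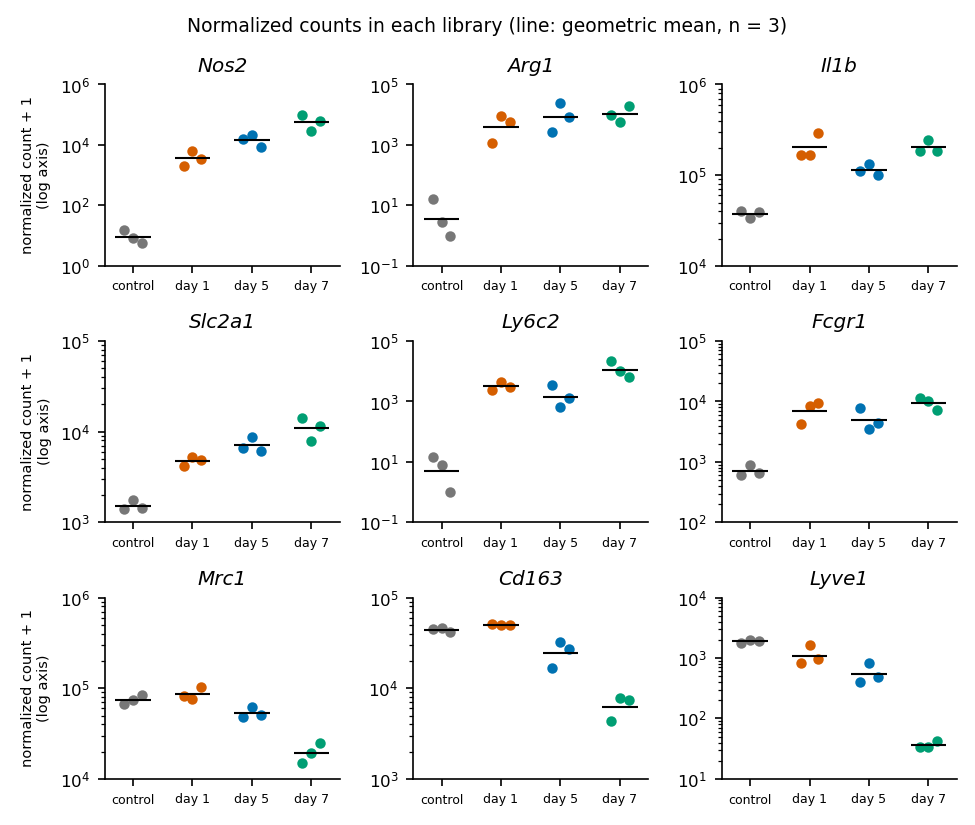
Normalized counts plus 1 of Nos2, Arg1, Il1b, Slc2a1, Ly6c2, Fcgr1, Mrc1, Cd163 and Lyve1 on a log axis, by group. Each dot is 1 library and each line the geometric mean of a group's 3 libraries. Nos2 lies highest on day 7, at a mean of 63531 against 8.97 in the control, and Lyve1 lowest on day 7, at 35.3 against 1903.

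On day 5 the lists of monocyte, cytokine and pattern recognition genes were again called higher than in the control, and genes induced by interferon gamma came first by the list test. Of 22 interferon gamma-induced genes 19 rose (22 adjusted over the list alone), with a median of 3.33, or 3.04 with genes at 0 in the control set to their bound (camera adjusted p = 1.67e-26, adjusted p = 0.024 with an estimated correlation). The guanylate-binding proteins, GTPases that act on pathogen vacuoles, led. Gbp4 went from 44.5 ± 46.9 to 3838 ± 1898 (113-fold, adjusted p = 2.06e-05, or 72.9-fold without control replicate 1 and 200-fold without control replicate 3). Gbp6 rose 56.2-fold and Gbp8 53.6-fold (23.5-fold without control replicate 2, 119-fold without control replicate 3). Nos2 reached 15264 ± 6409 (1570-fold, adjusted p = 7.5e-08) and Arg1 11620 ± 10950 (2310-fold, adjusted p = 1.67e-05). The fold of Arg1 was 4900 and 1230 without control replicate 1 or 3, and 3960 and 1350 without day 5 replicate 1 or 2. Of the 14 genes of their list 10 rose (11 adjusted over the list alone, median 3.77, camera adjusted p = 2.46e-14, adjusted p = 0.031 with an estimated correlation).

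Monocyte genes rose in 13 of 15 (13 adjusted over the list alone, median 4.98, camera adjusted p = 4.59e-19, adjusted p = 0.015 with an estimated correlation). Ly6c2 was at 1833 ± 1509 (300-fold, adjusted p = 3.69e-05), and its fold was 512 and 136 without control replicate 1 or 3 and 192 without day 5 replicate 1. Ms4a4c rose 125-fold, Ccr2 12.5-fold, and Hp was at least 487-fold higher, or 227-fold without day 5 replicate 2. Inhba rose 338-fold (213-fold without day 5 replicate 2). Fpr1 was at 1153 ± 213 and Plac8 at 1151 ± 865.4, against 1 and 2 reads in the control group. Of 17 cytokine genes 9 rose (13 adjusted over the list alone, median 1.18, camera adjusted p = 6.54e-12, adjusted p = 0.046 with an estimated correlation), with Il1b up 3.02-fold, while Il6 was not called (log2 change 0.64, adjusted p = 0.151). Pattern recognition receptors rose in 9 of 21 (12 adjusted over the list alone, median 0.76, camera adjusted p = 2.29e-09, adjusted p = 0.046 with an estimated correlation), Fpr2 95.8-fold and Clec7a 16.2-fold among them, and Tlr2 was not called (-0.41, adjusted p = 0.204). Type I interferon-stimulated genes rose in 17 of 26 (22 higher and 1 lower adjusted over the list alone, median 1.69, camera adjusted p = 3.88e-16, adjusted p = 0.12 with an estimated correlation), with Oas3 up 24.3-fold. Chemokines rose in 5 of 21 (7 adjusted over the list alone, median 0.74, camera adjusted p = 0.0012, adjusted p = 0.27 with an estimated correlation), Cxcl9 95.4-fold (47.4-fold without control replicate 1, 199-fold without control replicate 3) and Ccl5 6.76-fold among them. Of the oxidase and antimicrobial genes, 6 of 12 rose (7 adjusted over the list alone, median 0.81, camera adjusted p = 1.33e-06, adjusted p = 0.051 with an estimated correlation), with Slpi up 67.8-fold and Mpeg1, a pore-forming protein of phagosomes, 3.65-fold. NF-kappaB genes rose in 4 of 19 (4 higher and 1 lower adjusted over the list alone, median 0.34, camera adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation), with Traf1 up 5.28-fold. This list's call was lost without control replicate 2 (0.13).

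Glycolysis genes rose in 10 of 18 on day 5 (10 adjusted over the list alone, median 0.87, camera adjusted p = 1.15e-09, adjusted p = 0.12 with an estimated correlation). Slc16a3 rose 10.3-fold, Slc2a1 4.63-fold to 7200 ± 1427, Eno1 3.32-fold and phosphoglycerate kinase (Pgk1) 2.87-fold. Hypoxia-induced genes rose in 6 of 19 (9 adjusted over the list alone, median 1.11, camera adjusted p = 1.33e-06, adjusted p = 0.1 with an estimated correlation), Vegfa and Ddit4 each 7.00-fold and Hilpda, which blocks lipid breakdown, 3.74-fold. Hif1a rose 3.27-fold (adjusted p = 0.0165), a call lost without control replicate 1 (0.058), 2 (0.0587) or 3 (0.0589) or day 5 replicate 2 (0.0686) or 3 (0.0541). Respiratory chain and ATP synthase genes were called up as a list with a median of only 0.30 (camera adjusted p = 0.000854, adjusted p = 0.62 with an estimated correlation), a call lost without day 5 replicate 1 (0.16) and with fry (0.29). None of the 50 genes passed limma's threshold, over all genes or over the list alone. The tricarboxylic acid cycle (median 0.05), fatty acid oxidation (0.09), cholesterol synthesis (-0.21), lipid storage (0.30), lysosomal (-0.01, mean positive), matrix (0.14), cell cycle (0.29), interleukin 4 (0.39) and fibroblast (0.62) lists were not called, with camera adjusted p from 0.0744 to 0.652.

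MHC class II presentation (5 of 12 genes measured) had a median of 1.11 (camera adjusted p = 0.00265, adjusted p = 0.12 with an estimated correlation), and 2 genes rose (4 adjusted over the list alone). Without H2-Aa of the chromosome 17 stretch below, a test chosen after seeing the data, the median was 1.175 (adjusted p = 0.0025, 0.09 with an estimated correlation). The invariant chain gene Cd74, at 183030 ± 26710 against 68491 ± 14510 (adjusted p = 0.0271), and Ifi30 (adjusted p = 0.0258) depended on single libraries. Cd74 lost its call without any one of the 6, at adjusted p from 0.0596 to 0.126, and Ifi30 without control replicate 1 (0.102) or 3 (0.127) or day 5 replicate 1 (0.0832) or 3 (0.112). Resident macrophage markers fell in 4 of 26 (13 adjusted over the list alone, median -0.79, camera adjusted p = 1.33e-06, adjusted p = 0.27 with an estimated correlation). Lyve1, the hyaluronan receptor of perivascular macrophages, fell 3.51-fold, Stab1 2.35-fold and the transcription factor Maf 1.84-fold. Cd163 was not called (-0.84, adjusted p = 0.0606) except without day 5 replicate 2 (0.0392), and neither were Mrc1 (-0.49, adjusted p = 0.221) and Csf1r (-0.50, adjusted p = 0.159). Rasgrp3 (5.74-fold), Lbx1 (5.39-fold), Ank2 (4.51-fold) and Atp1b1 (4.43-fold) fell most among the named genes that kept their call throughout. Genes induced by tissue dissociation fell in 2 of 15 (2 adjusted over the list alone, median -0.28, camera adjusted p = 0.00876, adjusted p = 0.26 with an estimated correlation), Fosb 2.39-fold and Nr4a1 2.12-fold. Neutrophil genes rose in 5 of 9 (5 adjusted over the list alone, median 2.51, camera adjusted p = 6.58e-06, adjusted p = 0.031 with an estimated correlation), S100a8 93.2-fold (49-fold without control replicate 3) and the decoy receptor Il1r2 8.94-fold among them.

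Day 5 had 815 genes higher and 461 lower than the control by limma, 636 and 224 of them at least 2-fold. The total of 1276 fell to 778, 823 and 732 without control replicate 1, 2 or 3, to 775 without day 5 replicate 1 and to 682 without day 5 replicate 3. The authors' deposited table holds 1882 higher and 1476 lower. Of the named genes that were called under the 3 parts of the rule, 12 of 16, 50 of 56 and 10 of 11 stayed below the threshold whichever library was left out.

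On day 7 the markers of resident dermal macrophages had fallen in 20 of 26 genes (21 adjusted over the list alone), with a median of -2.12 (camera adjusted p = 2.72e-13, adjusted p = 0.11 with an estimated correlation). Lyve1 fell 52.7-fold, from 1903 ± 110.4 to 35.3 ± 5.25 (adjusted p = 6.9e-08). The lectins Cd209g and Cd209f fell 8.51-fold and 8.47-fold, Timd4, a receptor for dying cells, 8.43-fold, Cd163 7.00-fold (43972 ± 2370 to 6486 ± 1901) and Mrc1 3.85-fold. Monocyte genes rose in 12 of 15 (13 adjusted over the list alone, median 5.33, camera adjusted p = 8.25e-13, adjusted p = 0.055 with an estimated correlation), with Ly6c2 at 12844 ± 7984 (2340-fold, or 3990-fold without control replicate 1 and 1060-fold without control replicate 3), Ccr2 up 37.9-fold (24.8-fold without day 7 replicate 1) and Hp at least 769-fold higher. The neutrophil list was also called up (5 of 9 genes, 5 adjusted over the list alone, median 2.00, or 1.00 with bounds, camera adjusted p = 0.00107, adjusted p = 0.11 with an estimated correlation), with Il1r2 up 31.9-fold and the histidine decarboxylase Hdc 27.2-fold.

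Nos2 reached 63531 ± 34880 on day 7 (6180-fold, adjusted p = 8.76e-09) and Acod1 75677 ± 7436 (22.1-fold), and Arg1 was at 11750 ± 7471 (2900-fold, or 6170-fold without control replicate 1 and 1540-fold without control replicate 3). Of their list 11 genes rose and 3 fell (11 and 3 adjusted over the list alone, median 5.19, or 4.73 with bounds, camera adjusted p = 1.06e-07, adjusted p = 0.11 with an estimated correlation). Hmox1, which degrades haem and was among the most abundant transcripts of the control at 520490 ± 35900, fell 3.23-fold. Interferon gamma-induced genes rose in 21 of 22 (22 adjusted over the list alone, median 4.02, or 3.89 with bounds, camera adjusted p = 1.29e-19, adjusted p = 0.059 with an estimated correlation), Gbp4 462-fold, the GTPase Tgtp1 362-fold and Gbp8 194-fold. Gbp4 rose 299-fold without control replicate 1 and 820-fold without control replicate 3, and Gbp8 85.1-fold without control replicate 2 and 431-fold without control replicate 3. Tgtp1 rose 202-fold without day 7 replicate 1 and 588-fold without day 7 replicate 2. Type I interferon-stimulated genes rose in 22 and fell in 2 of 26 (22 and 3 adjusted over the list alone, median 2.11, camera adjusted p = 3.22e-11, adjusted p = 0.18 with an estimated correlation), Oas3 52.4-fold and Zbp1 45.7-fold, while Oasl1 fell 1.85-fold. The MHC class II list was called up (5 of 5 genes past the threshold, 5 adjusted over the list alone, median 2.46, camera adjusted p = 0.00086, adjusted p = 0.11 with an estimated correlation). Without H2-Aa of the chromosome 17 stretch, all 4 genes rose (median 1.78, camera adjusted p = 0.00193, adjusted p = 0.099 with an estimated correlation), with Cd74 up 5.48-fold to 389270 ± 160100 and the master regulator Ciita 9.57-fold.

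Glycolysis genes rose in 14 of 18 on day 7 (14 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 2.21e-09, adjusted p = 0.12 with an estimated correlation). Slc16a3 went from 552.3 ± 78.44 to 19340 ± 4310 (34.6-fold, adjusted p = 1.92e-08), Slc2a1 rose 7.11-fold, Eno1 6.55-fold and triose phosphate isomerase (Tpi1) 5.47-fold. Hypoxia-induced genes rose in 12 of 19 (13 adjusted over the list alone, median 1.59, camera adjusted p = 1.38e-06, adjusted p = 0.11 with an estimated correlation), with the HIF hydroxylase gene Egln3 up 46.8-fold (80.7-fold without day 7 replicate 2) and Vegfa 9.85-fold. Hif1a rose 2.92-fold (adjusted p = 0.0112), a call lost without day 7 replicate 1 (0.0533). Respiratory chain and ATP synthase genes rose in 13 of 50 (10 adjusted over the list alone, median 0.53, camera adjusted p = 1.22e-06, adjusted p = 0.66 with an estimated correlation), among them the succinate dehydrogenase genes Sdhd, 2.24-fold, and Sdhb, 2.22-fold. The fry test did not call that list (adjusted p = 0.055). The tricarboxylic acid cycle (5 of 17 higher, 3 lower, median 0.32), fatty acid oxidation (median 0.15), lipid storage (0.19), cholesterol synthesis (-0.22) and lysosomal (-0.36) lists were not called, with camera adjusted p from 0.296 to 0.5.

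Oxidase and antimicrobial genes rose in 8 of 12 on day 7 (9 adjusted over the list alone, median 1.28, camera adjusted p = 7.58e-06, adjusted p = 0.11 with an estimated correlation), Slpi 127-fold and Mpeg1 4.92-fold. Pattern recognition receptors rose in 13 and fell in 2 of 21 (14 and 2 adjusted over the list alone, median 0.95, camera adjusted p = 1.38e-06, adjusted p = 0.11 with an estimated correlation), Fpr2 193-fold and Clec7a 48.8-fold, whereas Tlr2 fell 2.08-fold (adjusted p = 0.000771). Cytokines rose in 8 of 17 (9 adjusted over the list alone, median 1.07, camera adjusted p = 3.5e-06, adjusted p = 0.12 with an estimated correlation), Inhba 520-fold (892-fold without day 7 replicate 2) and Il1b 5.36-fold, and Il6 was not called (0.35, adjusted p = 0.361). NF-kappaB genes rose in 9 and fell in 1 of 19 (10 and 1 adjusted over the list alone, median 0.59, camera adjusted p = 0.00285, adjusted p = 0.36 with an estimated correlation), with Traf1 up 10.4-fold and Nfkb1 down 1.95-fold. Fibroblast genes rose in 4 of 16 (5 adjusted over the list alone, median 1.13, camera adjusted p = 0.00492, adjusted p = 0.7 with an estimated correlation, fry adjusted p = 0.09), with Pi16 up 13.4-fold. Chemokines (4 higher and 4 lower of 21, 4 and 4 adjusted over the list alone), interleukin 4 genes (4 and 6 of 16), matrix genes (8 and 10 of 22), the cell cycle (1 and 1 of 26) and dissociation genes (1 and 5 of 15) were not called, with camera adjusted p from 0.283 to 0.837. For the interleukin 4, matrix and cell cycle lists the median, mean and test differ in sign. Csf2rb, the shared receptor chain for granulocyte-macrophage colony-stimulating factor, rose on days 1, 5 and 7 by 1.67, 1.65 and 1.77 on the log2 scale. Its partner Csf2ra and the proliferation marker Mki67 lay within 0.30 of the control on this scale with no call. Csf1r fell 1.66-fold, a call lost without control replicate 2 (0.057), control replicate 3 (0.0576) or day 7 replicate 1 (0.0551).

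Other genes far above the control on day 7 were Ly6i, a further Ly6 family gene, 1780-fold (3750-fold without control replicate 1), and Clic5, at 2660 ± 1865 against 1 read in the control group. Tppp (23.9-fold) and Atp1b1 (23.7-fold) were far below it. Tox2, a nuclear regulator, was 45.6-fold lower, but 17.3-fold without day 7 replicate 2 and 80.3-fold without day 7 replicate 3. Sema6a (25.6-fold lower, adjusted p = 0.0399) lost its call without any single one of the 6 libraries, at adjusted p from 0.0705 to 0.104. In all, limma called 1899 genes higher and 1828 lower on day 7, 1280 and 1164 of them at least 2-fold. The authors' deposited table holds 2428 and 2197. Of the named genes that were called under the 3 parts of the rule, 14 of 16, 59 of 64 and 13 of 15 stayed below the threshold whichever library was left out. With an estimated correlation camera called 4 of 31 lists on day 1, monocyte, neutrophil, inflammatory metabolism and pattern recognition genes, and on day 5 these, cytokines and interferon gamma-induced genes, 6 in all. It called 0 on day 7 and 0 between days, where the preset correlation gave 15 on day 7 and 11, 11 and 16 for day 5 against 1, day 7 against 1 and day 7 against 5.

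**Figure D4:**
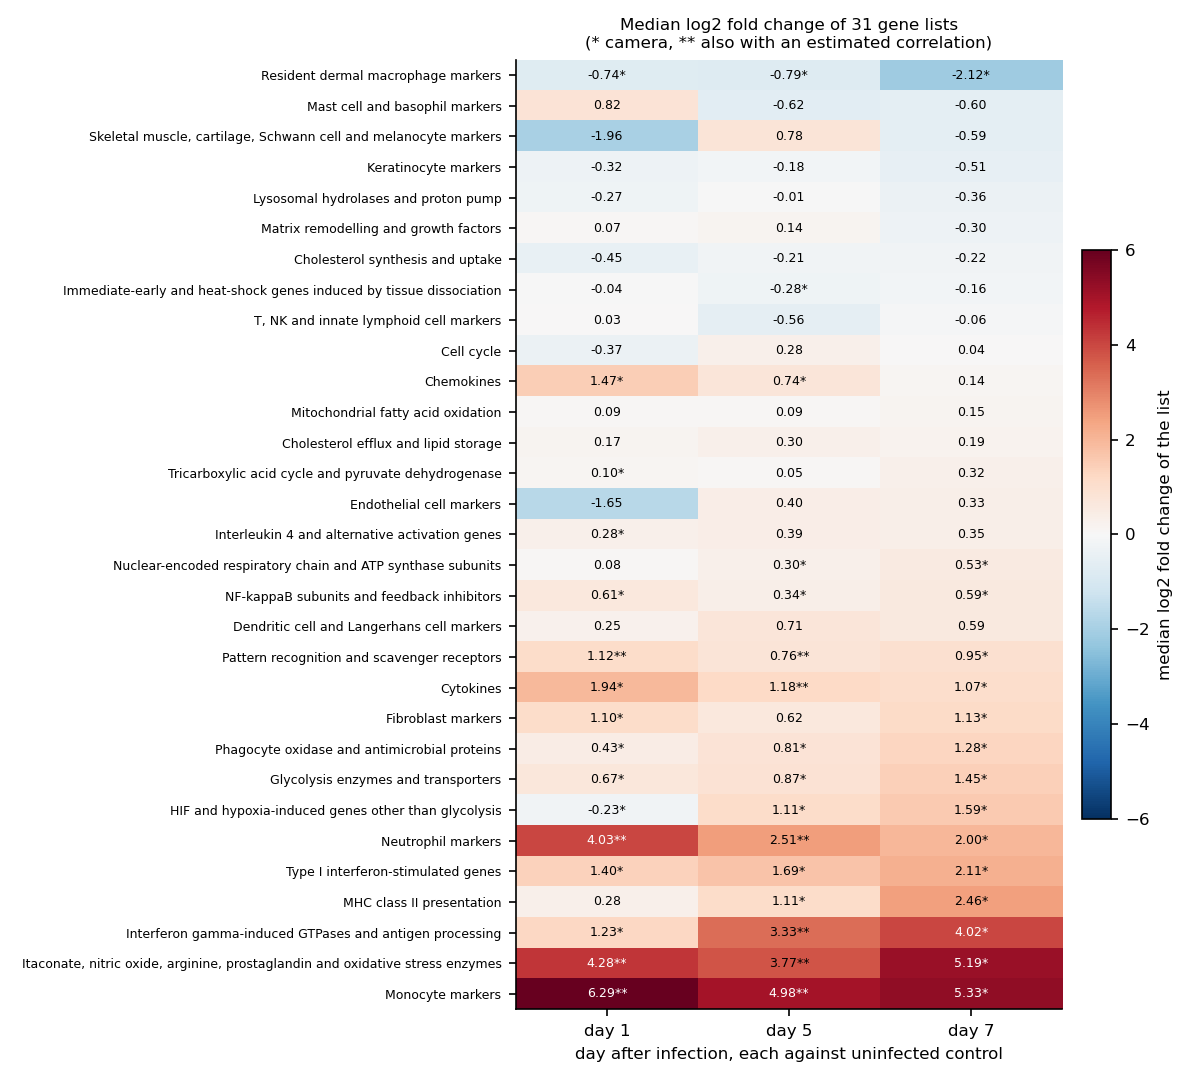
Heat map of the median log2 change of the tested genes of 31 lists on days 1, 5 and 7 against the control, with colours capped at 6 in either direction. A star marks a call by camera with the preset correlation and a pair of stars a call that also held with an estimated correlation. Monocyte genes lie highest, at 6.29, 4.98 and 5.33, and resident macrophage markers fall to -2.12 on day 7.

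The direct comparisons of days ask how the response moved on. From day 1 to day 5, interferon gamma-induced genes rose in 12 of 22 (15 adjusted over the list alone, median 1.85, camera adjusted p = 6.62e-13, adjusted p = 0.2 with an estimated correlation), with the GTPase Iigp1 up 16.8-fold (123.1 ± 35.8 to 2308 ± 1533). Gbp2b had 0 reads on day 1 and was at least 57.4-fold higher on day 5, or 24.7-fold without day 5 replicate 1. Monocyte genes fell in 2 of 15 (3 adjusted over the list alone, median -1.15, camera adjusted p = 3.19e-06, adjusted p = 0.2 with an estimated correlation), with Chil3 down 7.84-fold. Il2rb, a receptor chain of lymphocytes, fell 40.4-fold from 179.2 ± 108.3, or 20.5-fold without day 5 replicate 2 and 62.4-fold without day 5 replicate 3. Prss50 and Inpp5j rose 96.1-fold and 68.8-fold (201-fold and 144-fold without day 1 replicate 3), and the lysosomal protease Ctsh rose 2.2-fold. Mmp12, the macrophage elastase, rose 258-fold (adjusted p = 0.0124), a call lost without day 5 replicate 2 (0.0633) or 3 (0.0685). Its fold rests on 0 reads in day 1 replicate 1 and was 63.6 without that library. It was 494 and 546 without day 1 replicate 2 or 3, and 550 and 126 without day 5 replicate 1 or 2. NF-kappaB genes were called down as a list (median -0.27, camera adjusted p = 0.000575, adjusted p = 0.32 with an estimated correlation), with none of 19 genes past limma's threshold over all genes or the list alone, and fry did not call it (0.13). The other 8 lists called here had adjusted p from 0.25 to 0.73 with an estimated correlation. They were MHC class II (median 1.05), muscle, cartilage, Schwann cell and melanocyte (2.62, or 2.18 with bounds), the cell cycle (0.76), lysosomal (0.23) and endothelial genes (2.04, or 1.70 with bounds), called up, and mast cell (-1.06), tricarboxylic acid cycle (-0.12) and interleukin 4 genes (-0.18), called down. Without H2-Aa of the chromosome 17 stretch, the class II list had a median of 0.918 (camera adjusted p = 0.0377, adjusted p = 0.32 with an estimated correlation). Of its 4 genes, 0 passed limma's threshold and 3 did adjusted over the list alone. Without day 1 replicate 3 the calls of the MHC class II (adjusted p = 0.068), cell cycle (0.068), muscle (0.1), endothelial (0.094), mast cell (0.13), interleukin 4 (0.13) and lysosomal (0.27) lists were lost. Without day 1 replicate 1 those of the cell cycle, endothelial, mast cell (each 0.065), tricarboxylic acid cycle (0.094), interleukin 4 (0.11) and lysosomal (0.15) lists were lost. Day 1 replicate 2 or a day 5 library ended others at adjusted p from 0.051 to 0.15. Quantile normalization ended the muscle (median 1.04, adjusted p = 0.12), endothelial (0.83, 0.13), interleukin 4 (-0.37, 0.12) and tricarboxylic acid cycle (-0.13, 0.17) calls. The endothelial call was also lost with a pseudocount of 8 (0.061) or 0.5 (0.05) and with only these groups fitted (0.096). A pseudocount of 0.5 ended the interleukin 4 (0.05) and lysosomal calls (0.053), fitting only these groups the interleukin 4 call (0.052), and keeping genes from 50 counts the tricarboxylic acid cycle call (0.055). Fry did not call the lysosomal (0.2), tricarboxylic acid cycle (0.21), interleukin 4 (0.22) and mast cell lists (0.34). The number of lists called, 11, fell to 6 without day 1 replicate 1 and to 4 without day 1 replicate 3.

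Day 5 had 384 genes higher and 118 lower than day 1, 76.5% of them higher, or 60.6% after quantile normalization. The total of 502 moved with single libraries to 139, 128 and 73 without day 5 replicate 1, 2 or 3 and to 1002 without day 1 replicate 2. In all, 6 of the 16 genes with the greatest change and 4 of the 11 list members kept their call throughout. The authors' deposited table holds 295 higher and 282 lower. With only these groups fitted limma called 15 genes, and at an unadjusted p below 0.05 the fit of all libraries gave 2943.

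From day 1 to day 7, resident macrophage markers fell in 16 of 26 (17 adjusted over the list alone, median -1.28, camera adjusted p = 5.71e-12, adjusted p = 0.3 with an estimated correlation). Lyve1 fell 30.3-fold and Cd163 8.02-fold, from 50335 ± 854.9. Interferon gamma-induced genes rose in 17 of 22 (21 adjusted over the list alone, median 2.48, camera adjusted p = 1.27e-17, adjusted p = 0.16 with an estimated correlation), Tgtp1 331-fold, Gbp8 79.0-fold and Gbp4 61.0-fold, and Gbp2b was at least 299-fold higher, or 192-fold without day 7 replicate 1. Tgtp1 rose 215-fold without day 1 replicate 1 or 2, 783-fold without day 1 replicate 3, and 184-fold and 536-fold without day 7 replicate 1 or 2. Glycolysis genes rose in 11 of 18 (14 adjusted over the list alone, median 0.81, camera adjusted p = 1.56e-07, adjusted p = 0.32 with an estimated correlation), Tpi1 3.33-fold, Slc16a3 2.88-fold and the myeloid hexokinase Hk3 2.84-fold. Hypoxia-induced genes rose in 10 and fell in 1 of 19 (11 and 1 adjusted over the list alone, median 1.03, camera adjusted p = 0.00142, adjusted p = 0.38 with an estimated correlation), with Egln3 up 64.8-fold (24.6-fold without day 1 replicate 1, 168-fold without day 1 replicate 2, 112-fold without day 7 replicate 2) and Mxi1 down 1.55-fold. The MHC class II list was called up (5 of 5 genes past the threshold, 5 adjusted over the list alone, median 2.08, camera adjusted p = 0.000312, adjusted p = 0.17 with an estimated correlation). Without H2-Aa of the chromosome 17 stretch, all 4 genes rose (median 1.63, camera adjusted p = 0.00218, adjusted p = 0.2 with an estimated correlation), Ciita 6.73-fold (4.23-fold without day 1 replicate 2) and Cd74 4.22-fold. Interleukin 4 genes fell in 6 and rose in 2 of 16 (7 and 2 adjusted over the list alone, median -0.63, camera adjusted p = 0.000686, adjusted p = 0.17 with an estimated correlation), with Retnla, a secreted protein induced by interleukin 4, down 7.69-fold, Chil3 6.76-fold and Mrc1 4.46-fold. Matrix genes fell in 5 and rose in 2 of 22 (8 and 2 adjusted over the list alone, median -0.53, camera adjusted p = 0.00297, fry adjusted p = 0.11, adjusted p = 0.43 with an estimated correlation), with the metalloproteinase Mmp19 down 2.71-fold and Mmp12 up 462-fold (114-fold without day 1 replicate 1, where it had 0 reads, 885-fold and 977-fold without day 1 replicate 2 or 3, and 294-fold without day 7 replicate 3). Cxcl13, a B cell chemokine, fell 24.1-fold.

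Other lists called between days 1 and 7 each depended on single libraries. Respiratory chain genes rose in 6 of 50 (6 adjusted over the list alone, median 0.51, camera adjusted p = 6.14e-05, adjusted p = 0.76 with an estimated correlation), among them Sdhd, 2.09-fold, and Sdhb, 2.05-fold. The list was not called without day 7 replicate 2 (0.053) or by fry (0.13). Type I interferon-stimulated genes rose in 10 of 26 (11 adjusted over the list alone, median 0.64, camera adjusted p = 0.00185, adjusted p = 0.76 with an estimated correlation), a call lost without day 1 replicate 1 (0.052) and with fry (0.13). Oxidase and antimicrobial genes rose in 4 of 12 (5 adjusted over the list alone, median 0.44, camera adjusted p = 0.0113, adjusted p = 0.38 with an estimated correlation), with the oxidase subunit Cybb up 2.97-fold, a list call lost without day 1 replicate 1 (0.052) or 3 (0.072) or day 7 replicate 2 (0.059). Chemokines fell in 7 and rose in 2 of 21 (10 and 4 adjusted over the list alone, median -0.89, camera adjusted p = 0.0121, adjusted p = 0.51 with an estimated correlation), Ccl6 down 3.63-fold and Cxcl9 up 14.3-fold (9.13-fold without day 1 replicate 3). That call was lost without day 1 replicate 3 (0.083) or day 7 replicate 1 (0.057) and with fry (0.17). Day 7 had 1175 genes higher and 818 lower than day 1, 59% of them higher, or 47.1% after quantile normalization. The total of 1993 fell to 1101 without day 7 replicate 1, and 13 of 16 and 35 of 47 named genes kept their call throughout. The authors' deposited table holds 651 higher and 580 lower.

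Between days 5 and 7, resident macrophage markers fell in 11 of 26 (20 adjusted over the list alone, median -1.50, camera adjusted p = 1.89e-22, adjusted p = 0.21 with an estimated correlation). Lyve1 fell 15-fold and Cd163 3.92-fold, and outside the list Retnla fell 7.30-fold and the transferrin receptor Tfrc 2.77-fold. Glycolysis genes rose in 5 of 18 (11 adjusted over the list alone, median 0.57, camera adjusted p = 2.92e-09, adjusted p = 0.21 with an estimated correlation), with Slc16a3 up 3.37-fold. Interferon gamma-induced genes rose in 3 of 22 (12 adjusted over the list alone, median 1.05, camera adjusted p = 6.33e-11, adjusted p = 0.21 with an estimated correlation), with Socs1, a feedback inhibitor of that response, up 2.58-fold. Interleukin 4 genes fell in 4 of 16 (4 lower and 1 higher adjusted over the list alone, median -0.33, camera adjusted p = 0.00533, adjusted p = 0.21 with an estimated correlation), and of the lysosomal genes the proton pump subunit Atp6v0d2 fell 3.86-fold. Ly6a2, of the Ly6 family, rose 17-fold. Monocyte genes rose in 2 of 15 (6 adjusted over the list alone, median 1.03, camera adjusted p = 0.000614, adjusted p = 0.21 with an estimated correlation).

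Matrix (median -0.63), oxidase (0.46), hypoxia (0.41) and NF-kappaB (0.22) lists were also called between days 5 and 7, at camera adjusted p of 0.000759, 0.00112, 0.00238 and 0.00311, and with an estimated correlation at adjusted p from 0.21 to 0.44. In the oxidase and hypoxia lists no gene passed limma's threshold, although 3 oxidase genes did adjusted over the list alone. The remaining calls were lost without single libraries. They were respiratory chain genes (0.24, adjusted p = 0.48 without day 7 replicate 2), type I interferon (0.44, 0.061 without day 7 replicate 1), lysosomal (-0.36, 0.15 without day 7 replicate 1), MHC class II (1.02, 0.063 without day 7 replicate 2), fibroblast (0.84, 0.061 without day 7 replicate 1), pattern recognition (0.31, 0.077 without day 7 replicate 1) and chemokine genes (-0.54, 0.12 without day 5 replicate 1, 0.054 without day 5 replicate 2, 0.22 without day 7 replicate 1 and 0.16 without day 7 replicate 3). The chemokine call was also lost with only these groups fitted (0.14) and without the day 1 libraries (0.093). With an estimated correlation these had adjusted p from 0.21 to 0.57. Fry did not call any list of this paragraph except MHC class II, at adjusted p from 0.086 to 0.41, nor the monocyte list (0.086). Day 7 had 93 genes higher and 246 lower than day 5. The total of 339 fell to 64 without day 5 replicate 2, to 73 without day 5 replicate 3 and to 73 without day 7 replicate 1, and rose to 609 without day 7 replicate 2. Of the named genes, 6 of 16 and 8 of 27 kept their call throughout, the genes named here among them. The authors' deposited table holds 365 higher and 453 lower.

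Calls against the control overlapped between days. Days 5 and 7 shared 783 genes higher and 450 lower, where independent lists of these sizes would share 112.2 and 61.1. Days 1 and 7 shared 871 and 761 (165.1 and 202.7 for independent lists), and days 1 and 5 shared 578 and 311 (70.9 and 51.1). Log2 changes correlated across genes, which are not independent replicates, at r = 0.894 for days 5 and 7, 0.607 for days 1 and 7 and 0.609 for days 1 and 5, where simulated unchanged groups gave 0.501, 0.499 and 0.499 from the shared controls alone. The covariances were 1.474, 1.372 and 1.004 against simulated values of 0.26, 0.259 and 0.26. With 3 controls, no split leaves 2 libraries on either side, so part of the excess may come from the shared controls.

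Several genes central to this response could not be measured. Tnf, the major early cytokine of macrophages, was listed at 0 to 2.94 normalized counts in the 12 libraries and H2-Ab1, an MHC class II chain, at 0 in all. Both lie in a stretch of chromosome 17 from 33774900 to 35516837 that holds much of the major histocompatibility complex and whose bounds were chosen after its values were seen. Of its 107 protein-coding genes, 80 (74.8%) stayed under 10 in every library and 62 were at 0 throughout, against 33 of the 100 genes nearest on either side and 36.5% of 21371 protein-coding genes in all. Rps18, a ribosomal protein gene that every cell uses, was listed at 0. Exceptions include H2-K1, C4b, H2-Q4, Brd2 and Bag6, named after their values were seen. All 7 unmeasured genes of the MHC class II list and 3 of the 5 of the interferon gamma list lie there. Among the tested genes H2-Aa of the class II list and Tap1 and Psmb9 of the interferon gamma list also lie in it, and the others lie elsewhere, such as Cd74 on chromosome 18 and Gbp4 on chromosome 5. H2-Aa was listed at 4.14, 0, 9.91 and 39.7 normalized counts in the control and on days 1, 5 and 7. Without the genes of the stretch, the interferon gamma list was still called up in all 6 comparisons, at camera adjusted p of at most 2.87e-08, but with an estimated correlation only on day 5 (0.03). From day 5 to 7 the MHC class II list without H2-Aa had a median of 0.717 (adjusted p = 0.0147, 0.23 with that correlation, 0 of 4 genes called).

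Zeros were not confined to that stretch. Of 53 respiratory chain genes outside it, Ndufs3, Uqcrc1 and Atp5a1 were listed at 0 in all libraries, as was Rps10, 1 of 70 ribosomal protein genes. Trem2, Clec10a and Kif11, of the lipid, interleukin 4 and cell cycle lists, were at 0 as well. These genes were named after their values were seen. Among genes named above, Nos2 lies on chromosome 11 (78920787 to 78960226), Arg1 on chromosome 10 (24915207 to 24927470), Slc16a3 on chromosome 11 (120948484 to 120959000), Ly6c2 on chromosome 15 (75108161 to 75112066) and Lyve1 on chromosome 7 (110850607 to 110862953).

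**Figure D5:**
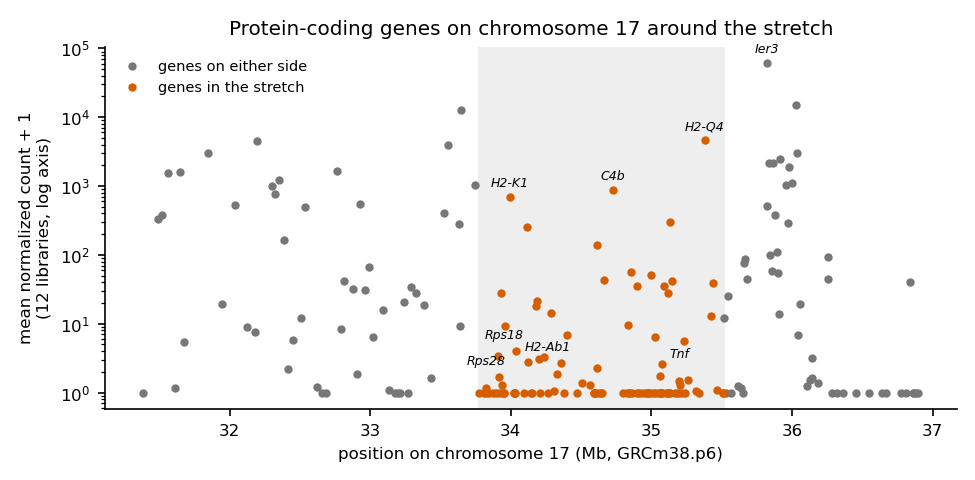
Mean normalized count plus 1 over the 12 libraries (log axis) of protein-coding genes against their position on chromosome 17 in megabases, with the stretch from 33774900 to 35516837 shaded. Most dots in the stretch lie near 1, with 62 of 107 genes at 0.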

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

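Of the tests below, the share of genes with 0 reads among those lower on day 1 and among abundant ones was chosen before that result was seen, and the count without day 1 replicate 1 and the comparison of opposite calls were chosen after.

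Gbp2b, Hk3 and Cd209e, which serve interferon defence, glucose phosphorylation and lectin binding, were called in opposite directions against the control on different days. The direct comparisons of days called 502, 1993 and 339 genes, and listed here are only genes called in opposite directions against the control on a pair of days, 1 for days 1 and 5, 16 for days 1 and 7 and 0 for days 5 and 7, where they were also named by the rule. Gbp2b, an interferon-induced GTPase, was at 10.4 ± 2.56 normalized counts in the control, 0 in all day 1 libraries, 189 ± 186 on day 5 and 985 ± 624 on day 7. It was called lower on day 1 (at least 3.16-fold, adjusted p = 0.00508) and higher on days 5 (adjusted p = 0.00626) and 7 (3.25e-05), and the days differed directly (adjusted p = 0.00152 for days 1 and 5 and 1.45e-05 for days 1 and 7), although with only days 1 and 5 fitted the adjusted p was 0.0666. No other Gbp gene was called lower on day 1. Hk3, the hexokinase of myeloid cells, was at 12330 ± 3151 in the control, 7099 ± 1186 on day 1 and 20195 ± 3239 on day 7 (direct adjusted p = 0.00117). Its day 1 call was lost without control replicate 1 (0.119) or 3 (0.115) or day 1 replicate 1 (0.0711) or 3 (0.0668), and its day 7 call without control replicate 2 (0.12) or day 7 replicate 1 (0.0943) or 3 (0.0662). Cd209e, a lectin of resident macrophages, rose by 1.41 to 1745 ± 523 on day 1 and was 2.63 below the control's 640 ± 7.37 on day 7, at 106 ± 32.3 (direct adjusted p = 2.39e-05). H2-Aa was listed at 4.14 ± 1.71 in the control, 0 on day 1 and 39.7 ± 12.7 on day 7 (direct adjusted p = 0.000928, 0.0514 with only these groups fitted). It lies in the stretch of chromosome 17 where most genes are near 0, so its calls are not read as expression. Its day 1 call was lost without any single one of the 6 libraries, at adjusted p from 0.0563 to 0.142.

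Genes lower on day 1, such as Ggnbp1 and Kifc2 with 0 reads in all day 1 libraries, may have lost reads to the low complexity of those libraries instead of falling in the cells. Of the 1529 genes called lower, 576 (37.7%) had 0 reads in at least 1 day 1 library, against 26.4% of all 13790 tested, which cannot tell a loss of transcripts from a fall. Of 597 lower genes with a control mean of at least 1000, 1 (0.2%) had 0 reads in a day 1 library, so abundant genes like Selenop and Csf1r were not called for lack of any reads, but a partial loss of reads would not reach 0 and was not tested. Without day 1 replicate 1, the library with the fewest genes, 1648 genes were called lower. The count does not show if they were the same genes. Whether the fall on day 1 lies in the cells or in the libraries is thus open for rare and abundant genes alike.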

How the results depend on the processing

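Tests with array quality weights, those without the genes of the chromosome 17 stretch and, in comparisons that do not use these libraries, those without the day 1 libraries or day 1 replicate 1 were chosen only after the result was seen.

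Ly6c2, Nos2, Slc16a3 and Lyve1 kept their calls on day 7 under every setting that could test them, while counts of genes moved. Over 376 results on named genes, 6266 of 6782 values under other settings were the same as in the fit used, 482 weaker, 16 stronger and 18 reversed. For lists, 1359 of 1531 values were the same and 172 weaker, 75 of these with an estimated correlation. Replicates have no order, and gene profiles with the same number in different groups correlated from -0.208 to 0.094 (4 of 12 libraries best with their own number). As a block, the replicate number changed the total for day 5 against day 1 to 289. The cause of these moves was not tested.

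Leaving out single libraries of the groups compared moved the totals to 1638 (without control replicate 3) to 2996 (without day 1 replicate 1) for day 1 against control, to 682 to 918 for day 5 and to 2747 to 3652 for day 7. They moved to 73 to 1002 for day 5 against day 1, 1101 to 2284 for day 7 against day 1, 64 to 609 for day 7 against day 5 and 2739 to 4430 among the 4 groups. With day 1 replicate 1, of neither group, left out, totals rose to 1743 and 4617 for days 5 and 7 against control. The total for day 7 against 5 rose to 503. Without the chromosome 17 stretch, totals were 2726, 1265 and 3716 on days 1, 5 and 7 against control. No list lost its call, but MHC class II had 4 genes (minimum 5). Lists called by camera ranged from 4 (without day 1 replicate 3) to 12 (without day 5 replicate 2) for day 5 against day 1. The calls shared by days 1 and 5 ranged from 539 to 1230, by days 1 and 7 from 1026 to 1927 and by days 5 and 7 from 671 to 1673.

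Array quality weights ran from 0.183 (day 1 replicate 1) to 4.088 (day 5 replicate 3). They gave 3914 and 6007 genes for days 5 and 7 against control, 2293 for day 7 against day 5 and 6066 among all groups. Shared calls rose to 1606 for days 1 and 5 and 3415 for days 5 and 7. DESeq2 gave 1947 for day 5 against control, 1155 for day 5 against day 1 and 890 for day 7 against day 5. With only the groups compared in the fit, limma gave 3084 for day 5 against control, 15 for day 5 against day 1, 353 for day 7 against day 1 and 180 for day 7 against day 5. Without the day 1 libraries it gave 1948 for day 5 against control and 591 for day 7 against day 5. The authors' deposited tables hold 3358 for day 5 against control, 1231 for day 7 against day 1 and 818 for day 7 against day 5. For day 5 against day 1, quantile normalization gave 246, no filter 208, the filter at 50 gave 156 and edgeR 324, and for day 7 against day 5 quantile normalization gave 523. With an estimated correlation camera called 4 lists on day 1, 6 on day 5 and 0 in each other comparison. For day 5 against day 1, no filter gave 17 lists and fry 6, and for day 7 against day 5 fry gave 5.

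Of the genes near 0, Csf2ra on day 1 (-0.03 against the control) became 0.04 without control replicate 1, 0.10 without control replicate 3, 0.03 without day 1 replicate 2, 0.02 without day 1 replicate 3 and -0.23 without control replicate 2. On day 7 it went from 0.04 to -0.024 with quantile normalization, -0.11 with array quality weights, -0.16 without control replicate 2, -0.07 without day 7 replicate 1 -0.02 without day 7 replicate 2 and 0.20 without day 7 replicate 3. Tlr2 on day 1 (-0.02) became 0.024 without control replicate 3, 0.018 without day 1 replicate 2 and -0.061 without day 1 replicate 3. Mki67 on day 1 (-0.07) became 0.12 without control replicate 1, 0.04 without control replicate 3, 0.07 without day 1 replicate 2 and -0.36 without control replicate 2. On day 7 it went from -0.05 to 0.12 with array quality weights, 0.14 without control replicate 1, 0.05 without control replicate 3, 0.19 without day 7 replicate 1 and -0.344 without control replicate 2. None of these was called, so their direction is not known.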

Other observations

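All tests in this part were chosen after the results were seen, those on gene families among them.

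Gene families from shared name stems, 203 with at least 8 tested members, were run beside the fixed lists. On day 1, 7 of 13 Psmd genes, of the proteasome's regulatory particle, rose (median 0.54, camera adjusted p = 0.00037, adjusted p = 0.98 with an estimated correlation). On day 7, 7 of 7 Psmb genes of its catalytic core outside the chromosome 17 stretch rose (median 0.903, camera adjusted p = 0.004, adjusted p = 0.97 with an estimated correlation). The guanylate-binding Gbp family, 8 of whose members stand on the fixed lists, rose in all 11 on day 5 (median 4.23, camera adjusted p = 2.7e-16, adjusted p = 0.5 with an estimated correlation) and on day 7 (median 6.28, camera adjusted p = 6.1e-12, adjusted p = 0.77 with an estimated correlation). Matrix metalloproteinases of the Mmp family rose in 7 of 14 on day 5 (median 2.40, camera adjusted p = 1.9e-05, adjusted p = 0.53 with an estimated correlation). Slfn genes, which restrict growth and viruses, rose in 6 of 10 on day 7 (median 1.90, camera adjusted p = 0.012, adjusted p = 0.95 with an estimated correlation). Clec lectins rose in 9 of 22 on day 7 (median 0.98, camera adjusted p = 0.0016, adjusted p = 0.77 with an estimated correlation). Nucleolar Nop genes fell in 4 of 8 on day 5 (median -0.77, camera adjusted p = 0.0044, adjusted p = 0.78 with an estimated correlation) and splicing factors of the Srsf family in 3 of 11 (median -0.36, camera adjusted p = 0.0051, adjusted p = 0.64 with an estimated correlation). Reads at Snora genes (small nucleolar RNAs) fell in 8 of 23 on day 1 (median -2.56, camera adjusted p = 0.002, adjusted p = 0.8 with an estimated correlation), in the libraries with fewest genes. Their source in polyadenylated RNA was not tested. With an estimated correlation camera called 0 families throughout.

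Resident markers such as Lyve1, Cd163 and Timd4 fell on day 7 while Ly6c2, Ccr2 and Hp rose, which may mean that incoming monocyte-derived cells diluted the resident cells or that resident cells changed their expression. Sorted neutrophils would raise neutrophil genes. Their day 7 median was 3.65 (4.3 over 17 with any read) against 3390 for monocyte genes. With 11 of 18 under 10 but S100a8 at 409.5 and Hdc at 4519, a minority is not excluded. Dilution alone would lower every resident marker to a similar degree. The log2 changes had an SD of 1.23 around a median standard error of 0.35, from -5.72 for Lyve1 to -0.01 for C1qb, but incoming cells may make some of these transcripts, so the test cannot tell dilution from a change within cells. Single-cell profiles or a fate label would separate the explanations.

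Tnf, H2-Ab1 and Rps18 were listed at or near 0 along with most genes in a stretch of chromosome 17, which is unlikely in macrophages that make ribosomes. If genes were merely silent in these cells, the ribosomal protein genes there, which all cells use, would still be read like those elsewhere. Rps18 and Rps28 had a mean of 0.075 against a median of 6855 for 70 ribosomal protein genes elsewhere, which argues against true absence. Reads that also match alternate haplotype sequences of the assembly could have been dropped as matching several places, and 62 of 107 genes were at 0 in all libraries, but the files hold no reads and cannot tell. Values of this stretch should not be read as expression.

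Other groupings of the libraries were fitted for the totals of genes and lists. Over 100 ways to group the 12 libraries, the true grouping alone reached 3879 genes by the F test, the highest other grouping giving 2055, so a grouping by chance is unlikely to explain that result (1 of 100). For each pair of groups only 10 splits exist, too few for a share under 0.05. The true split gave the most genes in all 6 comparisons (1 of 10 each), with at most 1, 0, 0, 0, 35 and 1 genes for other splits in the order day 1, 5 and 7 against control, day 5 against 1, day 7 against 1 and day 7 against 5. For lists called by camera with the preset correlation, 1, 5, 3, 2, 2 and 1 of 10 splits gave as many as the true one, and other splits reached 14, 18, 19, 12, 11 and 14 lists. These other splits keep part of the difference between the groups.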
